A study of Mus musculus with 2 samples.

How the data were processed

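Adherent cells from the bone marrow of 1 mouse were cultured with DHT or its ethanol vehicle and sequenced as 2 droplet-based 3′ gene expression libraries, 1 per group, per the labels' protocols. The authors deposited, for each library, a sparse matrix of raw UMI counts per gene and barcode, with the lists of genes and barcodes. Cell Ranger 7.0.1 made the counts, per the file headers and the submitters' processing notes. Those notes name the builds GRCh38 and mm10 without a role, and the gene identifiers are those of mouse. How barcodes were called as cells, whether intronic reads were counted and whether strand was used are not given in the sources used here. Both gene lists held the same 32285 genes. Of these identifiers 32235 (99.8%) matched GENCODE release M21 (GRCm38, the same assembly as mm10), which supplied gene positions.

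Before the data were examined, the gene lists, the markers, the cell filter, the size rule and the alternatives below were fixed. Barcodes with at least 300 genes, at least 800 UMIs and at most 10% of UMIs from mitochondrial genes were kept. The filter removed 2887 barcodes of the DHT library and 1884 of the vehicle library. More than 10% mitochondrial UMIs were found in 17.4% and 14.6% of barcodes, and too few UMIs or genes in 12.3% and 4.66%. Doublets were called in each library with Scrublet at an expected rate of 0.08 and an automatic threshold, and 203 (2.57%) and 174 (1.99%) were removed. This left 7708 and 8572 cells with 296926780 and 429488169 UMIs. Gm42418, a locus that collects ribosomal RNA, took 3.26% and 2.71% of them.

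Clustering used scanpy 1.11.5 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 under Python 3.11.15. Counts were scaled to 10000 per cell and logged. The 2000 most variable genes, without both interferon lists, gave 30 principal components, a graph of 15 neighbours and Leiden clusters (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.6. Leaving out the interferon lists keeps their genes from setting the clusters. Members of the other lists, such as the osteoclast and cell cycle genes, were not left out and could set them. Each of the 16 clusters was compared with the median of the other clusters, after adding 10 CPM. It was called X-like when X had the most markers among its 10 leading genes, and at least 3 and at least 50% of X's markers were over 2-fold higher. This scoring rule was chosen after the clusters and their numbers of cells in each library were seen, and before genes were compared between groups. The scoring tried first, against all other cells, left clusters 0 and 1 unnamed, which would have made neutrophil-like cells (1720 and 995) the largest named class. It was kept as an alternative. Markers of 19 cell types were used and 9 types gave a class. Clusters with a median under 2000 UMIs were not named. Classes with at least 100 cells in both libraries, 7 in all, were compared between groups.

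Counts were summed over the cells of a library, or of a class within it, and divided by their total to give CPM. Cells are not replicates, so no p-value, standard error or test was made. CPM have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95% and for counting error only. A gene was counted as higher or lower at a ratio of at least 1.5-fold among genes with at least 20 CPM in 1 or both libraries. Named genes are the 12 highest and 12 lowest of these, without mitochondrial, ribosomal protein, immunoglobulin, Xist, Y-linked and predicted genes. To them come list members at 1.5-fold, the 2 highest and 2 lowest members of each list, and 18 genes fixed by name. Of each of 20 fixed lists, members with at least 2 CPM were measured, and a library at 0 was set to a floor of 3 counts. The list's median log2 ratio was placed among 10000 random lists of the same size, matched on expression in 20 bins. That percentile describes these libraries and is not a test. Mx1, Mx2 and Mnda of the type I interferon list were not analysed here. For shares of cells with a UMI, each cell was thinned to the 10th percentile of UMIs (4723), and shallower cells were left out.

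The steps were tested on simulated counts drawn from the libraries' means, with 200 genes changed. In the simulation of all cells and in that of osteoclast-like cells, 100% of genes changed 2-fold and 0% of those changed 1.2-fold passed the 1.5-fold rule, as did 0% of 6339 and 6155 unchanged genes. Intervals held the true ratio in 95.0% and 94.9% of genes. The simulated counts held counting error only, which is what the intervals assume. They cannot show how often 2 libraries of the same group would differ by 1.5-fold.

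The alternatives were scaling by TMM or median of ratios, the mean of each cell's own CPM, and thinning of the deeper library. Others were mitochondrial limits of 5 and 20%, at least 1000 genes and 2000 UMIs, no doublet removal, removal of the 10% of cells with the highest Scrublet score, and CPM minimums of 5, 20, 50 or none. The class weights, resolutions of 0.3 and 1.0, clustering with all variable genes and clusters from the vehicle library alone were varied too. TMM and median of ratios shifted log2 ratios by 0.07 and 0.08 in all cells and by 0.05 and 0.06 in osteoclast-like cells. Figures were drawn with matplotlib 3.10.9.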

Results

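Single-cell RNA sequencing was carried out on adherent cells grown from the marrow of a male C57BL/6J mouse aged 3 months, under conditions that drive osteoclast formation together with inflammation. The cells were kept for 48 h in hormone-depleted medium with 5 ng/mL M-CSF, the growth factor of the monocyte lineage. They then received 100 ng/mL M-CSF, 30 ng/mL RANKL, the cytokine that starts osteoclast differentiation, and 10 ng/mL human TNF for 24 h. One culture contained 1 nM dihydrotestosterone (DHT), an androgen, throughout, and the other its ethanol vehicle. The design gives a single comparison, DHT against vehicle, with 1 library per group, so no difference below has a replicate check and no test between groups was made. The DHT library held 319430510 unique molecular identifiers (UMIs), a median of 13838 per barcode, and the vehicle library 453802415, a median of 43120. After filtering, 7708 DHT cells (71.4% of barcodes, median 30149 UMIs) and 8572 vehicle cells (80.6%, median 50815 UMIs) remained. All intervals are 95% intervals that cover counting error only, and ratios are of counts scaled to the total of the cells compared (CPM), DHT over vehicle.

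The first question was which cells the cultures held. Osteoclast-like cells, a class of 3 clusters, were the largest class in both libraries under the main settings. They made up 29.1% of DHT cells (2242 of 7708, exact binomial interval 28.1 to 30.1%) and 55.5% of vehicle cells (4759 of 8572, 54.5 to 56.6%), a share ratio of 0.524. Neutrophil-like cells, with S100a8 and S100a9 among the leading genes of each cluster, made up 22.3% of DHT cells (21.4 to 23.3%) and 11.6% of vehicle cells (10.9 to 12.3%), a ratio of 1.92. B cell-like cells made up 4.49% (4.04 to 4.98%) and 1.38% (1.14 to 1.65%).

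The 3 osteoclast-like clusters differed in their level of Acp5. Cluster 3, with 520 and 985 cells, had it at 1370 and 1208 CPM. Cluster 0 (1085 and 2317 cells) had it at 249 and 166 CPM, and cluster 1 (637 and 1457 cells) at 323 and 270 CPM. Mki67, a gene of dividing cells, was at 287 and 280 CPM in cluster 0 and higher still in cluster 1, against 68.1 and 66.7 CPM in cluster 3. Clusters 0 and 1 were not told apart from osteoclast precursors. The size of the class depended on its naming. With clusters scored against all other cells, the scoring tried first, clusters 0 and 1 had no name, osteoclast-like cells were 6.75% and 11.5%, and neutrophil-like cells were the largest named class. Part of the class also lost its name at resolution 0.3 (15.6% and 30.0%), at resolution 1.0 (18.7% and 34.5%), at mitochondrial limits of 5% (17.9% and 33.4%) and 20% (19.0% and 35.8%), and with at least 1000 genes and 2000 UMIs (19.2% and 32.9%). In each of these settings the DHT library held more neutrophil-like than named osteoclast-like cells. A smaller part lost its name with all variable genes (24.6% and 44.0%) and with clusters from the vehicle library alone (22.3% and 39.8%). The same held without the 10% of cells with the highest Scrublet score (24.0% and 41.5%). The share ratio lay between 0.503 and 0.587 over all settings.

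Monocyte-like cells (F13a1, Vcan, Ccr2, Ly6c2) were 7.78% of the DHT library and 5.75% of the vehicle library. Granulocyte-monocyte progenitor-like cells (Elane, Mpo, Prtn3, Ctsg, Ms4a3) were 8.73% and 6.15%. The border between these classes moved: at resolution 1.0 they were 11.3% and 8.96% (monocyte-like) and 5.03% and 2.92% (progenitor-like), and with clusters from the vehicle library alone 12.1% and 9.65%, and 7.30% and 4.08%. Both shares were higher with DHT in every setting. Macrophage-like cells (C1qa, Ms4a7, Apoe) were 12.4% (11.6 to 13.1%) and 12.6% (11.9 to 13.3%). No direction is given for them, as they were 11.4% and 9.90% at resolution 0.3 but 12.9% and 14.5% with clusters from the vehicle library alone. Conventional dendritic cell-like cells were 1.88% and 2.19%. Mesenchymal stromal-like cells (24 and 12 cells, 15 and 7 at resolution 0.3) and plasmacytoid dendritic cell-like cells (19 and 15 cells) were rare. Clusters with a median under 2000 UMIs, a limit set after the clusters were seen, were left unnamed and held 12.8% of DHT cells and 4.47% of vehicle cells. Most of these were 1 cluster (930 and 383 cells) with Ms4a7, Apoe, C1qa, C1qb and C1qc among its leading genes. Counted with the macrophage-like cells, it gave 24.4% of DHT cells and 17.1% of vehicle cells. Among osteoclast-, macrophage-, monocyte- and progenitor-like cells alone, osteoclast-like cells were 50.2% (48.7 to 51.6%) of 4469 DHT cells and 69.4% (68.3 to 70.5%) of 6861 vehicle cells. Among osteoclast- and macrophage-like cells they were 70.2% (68.5 to 71.7%) and 81.5% (80.5 to 82.5%). The 3 osteoclast-like clusters kept similar proportions, at 48.4%, 28.4% and 23.2% of the class with DHT and 48.7%, 30.6% and 20.7% with vehicle. Collection of adherent cells only and the lower depth of the DHT library can both set shares. That lower depth was not found in every class compared. Median UMIs per cell were higher with DHT in neutrophil-, monocyte-, progenitor- and B cell-like cells. They were 58152.5 with DHT and 59531 with vehicle in osteoclast-like cells, and lower with DHT in macrophage- and dendritic cell-like cells.

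**Figure D1:**
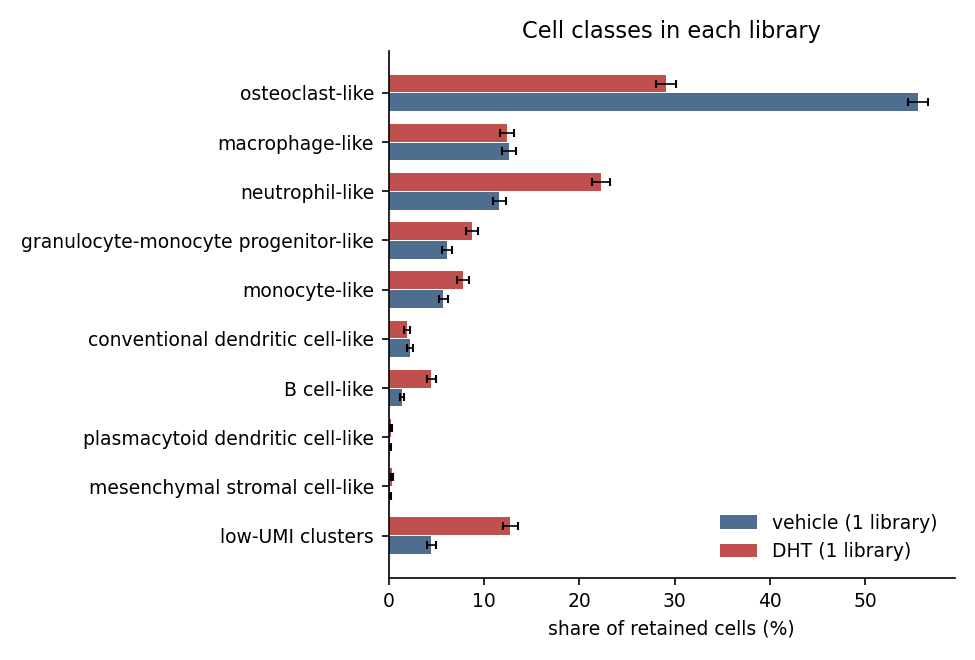
Share of retained cells (x axis, %) in each cell class (y axis) in the DHT and the vehicle library, 1 library each; bars are shares and error bars exact 95% binomial intervals. Osteoclast-like cells were 29.1% with DHT and 55.5% with vehicle, and neutrophil-like cells 22.3% and 11.6%.

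Within osteoclast-like cells, interferon-stimulated genes stood apart from the rest of the transcriptome. Isg15, a ubiquitin-like modifier, was at 84.7 CPM (83.2 to 86.3) with DHT and 6.38 CPM (6.10 to 6.68) with vehicle, 13.3-fold higher (12.6 to 13.9). Oasl2, of the 2′-5′ oligoadenylate synthetase family, was 17.3-fold higher, Rtp4 11.5-fold higher and Irf7, a transcription factor of the interferon response, 10.4-fold higher. In the GRCm38 annotation Isg15 lies on chromosome 4 (156199424 to 156200818), Oasl2 on chromosome 5 (114896936 to 114912234) and Irf7 on chromosome 7 (141262706 to 141266481).

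Of 6492 genes with at least 20 CPM in 1 or both libraries, 70 were at least 1.5-fold higher in the osteoclast-like cells of the DHT library and 7 were at least 1.5-fold lower. The 12 highest were Oasl2, Isg15, Rtp4, Irf7, Oas3 (log2 ratio 2.49), Slfn5 (2.45), Ddx58, a sensor of viral RNA (2.38), Ly6a (2.30), Oas2 (2.26), Csta2 (2.16), Xaf1 (2.03) and Trim30a (1.75). Csta2 belongs to a family of near-identical genes and its count is uncertain, as are those of the Slfn genes. The lower genes included Hmga2, a chromatin protein (log2 ratio −0.83, 14.9 against 26.5 CPM), Kcnk13 (−0.68), Pmp22 (−0.64), Psd3 (−0.61) and Mgst3 (−0.61). The count of 7 lower genes was 1 to 9 over the other scalings, cell filters, clusterings and namings, and several of these genes lay close to the 1.5-fold limit.

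The fixed list of type I interferon-stimulated genes had 52 measured members in osteoclast-like cells. Of these 48 were at least 1.5-fold higher, none was as much lower, and 4 lay in between. Their median log2 ratio was 1.71, above all 10000 random lists matched on expression, whose central 95% ran from −0.01 to 0.08. Bst2 (273 against 137 CPM) was among the most abundant members. Slfn9 (0.21) and Tor3a (0.30) had the smallest ratios among members with at least 20 CPM. Of interferon gamma-inducible GTPases and antigen processing genes, 17 of 28 were at least 1.5-fold higher and none lower, with a median of 0.86. Among its members with at least 20 CPM, H2-Q7 (1.70) and Irgm1 (1.67) had the largest ratios, and the immunoproteasome subunit Psmb8 (0.19) and Cd274 (0.22) the smallest. H2-Q7 shares near-identical sequence with other H2-Q genes. Together the interferon lists held 33 of the 70 higher genes.

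Markers of other cell types were also higher in these cells. S100a9 was at 473 CPM against 172 CPM, S100a8 at 378 against 147 CPM and Camp at 94.8 against 38.1 CPM. These genes reached only 2.63 to 3.25% of their level in all barcodes of the same library. Of the higher genes, 5 were neutrophil markers. When free RNA was estimated from such markers and subtracted, an alternative chosen after seeing the data, 60 genes remained higher, 59 of them among the 70. All 33 interferon list genes stayed in that count and no neutrophil marker did. The loss of the markers was largely set in advance, since the share subtracted was estimated from them. The same subtraction turned the log2 ratios of Lcn2 and Chil3 from 1.66 and 1.36 to −0.91 and −1.54. The share subtracted was a median, 3.54% with DHT and 3.25% with vehicle. Single markers ran from 2.63 to 11.5% and from 3.02 to 27.7%, so these negative ratios are not read as lower expression. Of MHC class II genes 5 of 9 members were higher, with a median of 0.72, but H2-Eb1, at 22.9 against 12.2 CPM, went from 0.91 to −0.035 when the 10% of cells with the highest doublet score were removed.

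**Figure D2:**
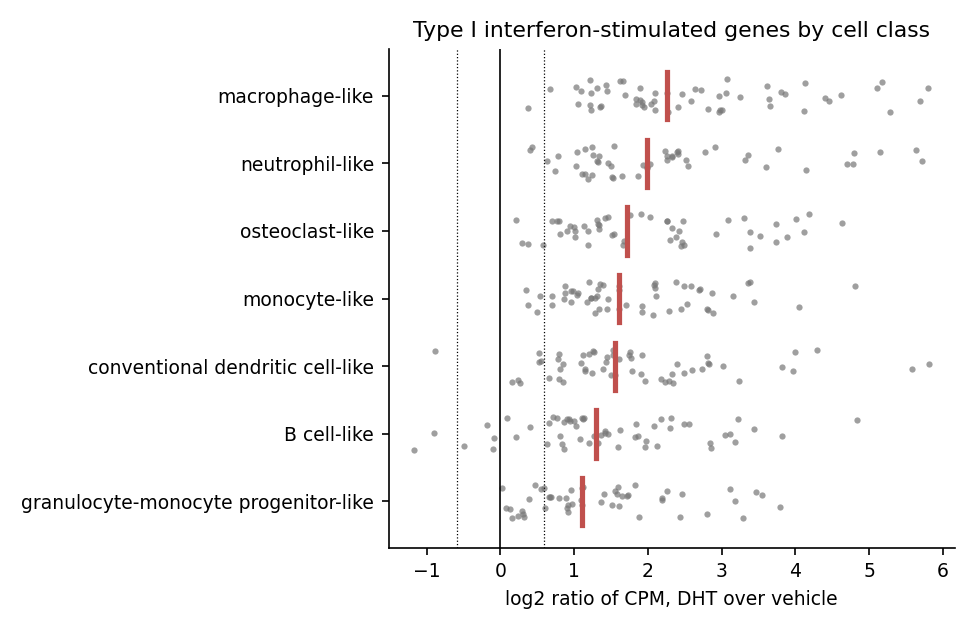
Log2 ratio of CPM, DHT over vehicle (x axis), of each measured type I interferon-stimulated gene (grey points, with vertical scatter added for visibility) in 7 cell classes (y axis), 1 library per group; red bars are medians and dotted lines mark 1.5-fold. The median was 1.71 in osteoclast-like, 2.26 in macrophage-like and 1.10 in granulocyte-monocyte progenitor-like cells.

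Osteoclast genes were slightly higher within the osteoclast-like cells of the DHT library, by far less than the interferon genes. The matrix protease Mmp9 had a ratio of 1.97-fold (1.95 to 1.99), at 520 against 264 CPM, and the membrane protease Mmp14 of 1.63-fold. Acp5, the tartrate-resistant acid phosphatase, was at 538 against 418 CPM (log2 ratio 0.36), and Ocstamp, a fusion factor, at 75.9 against 59.8 CPM (0.34). Ctsk, the collagen-degrading cathepsin, had a log2 ratio of 0.24, Nfatc1, the master transcription factor of osteoclasts, 0.20, and Dcstamp 0.16. Tnfrsf11a, the receptor of RANKL, was at 310 and 308 CPM. Over the list of osteoclast differentiation and resorption genes, 4 of 38 measured members were at least 1.5-fold higher (Mmp9, Mmp14, Itgb3 and Rab38), none was as much lower, and the median was 0.19 against −0.03 to 0.07 for random lists. Trem2 had the lowest ratio (−0.48). The difference was not even over the class. In cluster 3 Atp6v0d2 (0.0033), Dcstamp (0.0080) and Nfatc1 (0.07) were near 0, Ctsk was at 0.12, Acp5 at 0.18 and Mmp9 at 0.65. In cluster 0 Ctsk was at 0.34, Acp5 at 0.59 and Mmp9 at 1.22, and in cluster 1 at 0.042, 0.26 and 0.98. The list's medians in clusters 0, 1 and 3 were 0.19, 0.11 and 0.11. Cluster 3, with the highest level of Acp5, made up 23.2% of the class with DHT and 20.7% with vehicle. The mix of clusters can therefore add to the ratios of the whole class. Several of these genes also served to name the class.

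After each cell was thinned to 4723 UMIs, Acp5 was detected in 52.9% of osteoclast-like DHT cells (50.8 to 55.0%) and 46.5% of vehicle cells (45.1 to 47.9%). In neutrophil-like cells it was detected in 5.77% and 7.32%, a background level. Thinning left out 1058 DHT and 570 vehicle cells of lower depth. Mmp9 was detected in 62.6% against 41.3%, with 15.3% (45 of 294) and 11.5% (6 of 52) in B cell-like cells. Without thinning, Acp5 was in 87.3% and 86.0% and Mmp9 in 93.9% and 81.5% of osteoclast-like cells. Median depths before thinning were 58650 and 59743 UMIs in osteoclast-like cells, 12991 and 10624 in neutrophil-like cells and 6577 and 5653 in B cell-like cells. Calcr, the calcitonin receptor of late osteoclasts, was in 5 of 2242 DHT cells and 5 of 4759 vehicle cells without thinning, too few to compare.

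**Figure D3:**
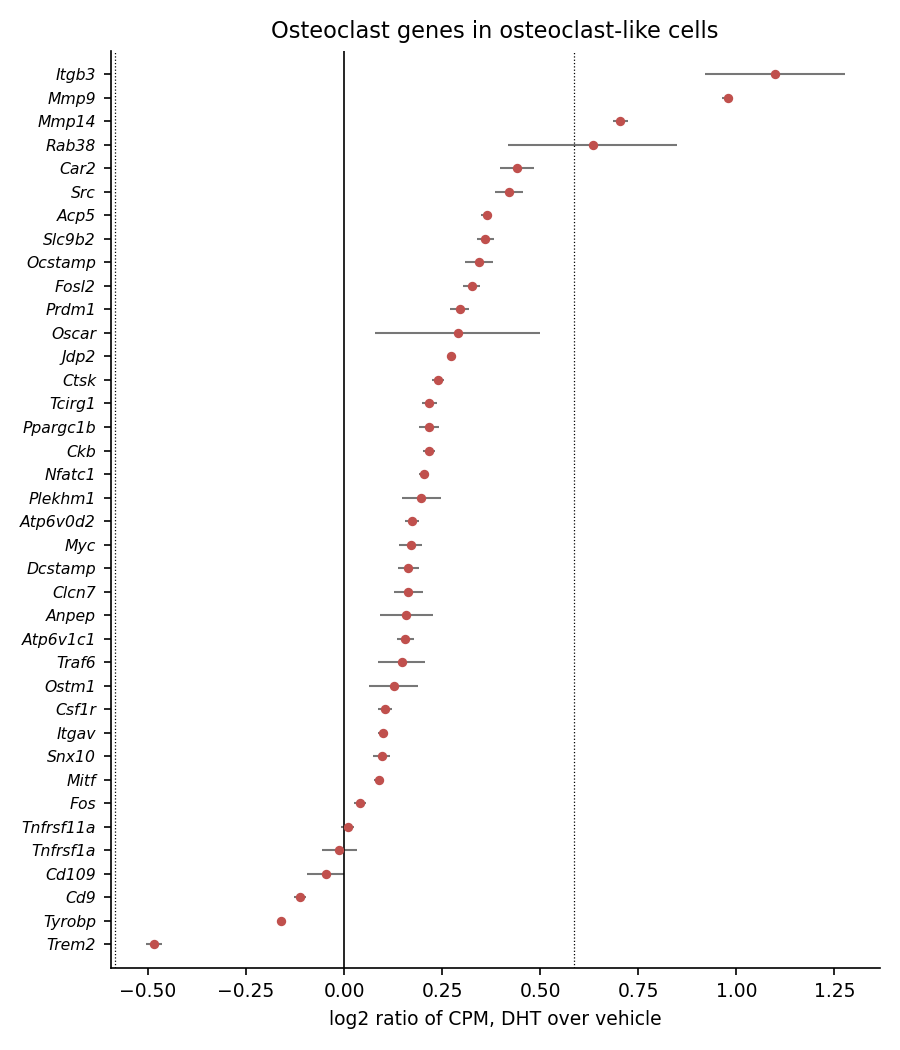
Log2 ratio of CPM, DHT over vehicle (x axis), of each measured gene of the osteoclast list (y axis) in osteoclast-like cells, 1 library per group, with exact 95% conditional binomial intervals; dotted lines mark 1.5-fold. Most genes lie slightly above 0, with Mmp9 at 0.98 and Trem2 at −0.48.

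The other fixed lists moved little within osteoclast-like cells. Repressors of osteoclast differentiation had a median of −0.02, with 2 of 19 members lower and none higher. The interferon regulator Irf8, one of these repressors, was at 6.94 against 7.49 CPM. NF-κB and inflammatory cytokine genes had a median of 0.07. Of their 31 members 5 were higher, among them Lcn2 and Il1rn (0.92), and none was lower. Tnf was at 12.9 and 12.8 CPM, and Il1b at 2.22 and 0.998 CPM. No member of the S phase list (median −0.03), the G2 and M phase list (0.07), the list of immediate early and dissociation stress genes (0.07) or the androgen and steroid response list (0.03) reached 1.5-fold. The same held for oxidative phosphorylation (−0.02), lysosome and V-ATPase (0.11), cholesterol synthesis (0.02), the unfolded protein response (0.12) and interferon ligands, receptors and sensors (0.07). Glycolysis and hypoxia (0.02), lipid uptake (0.10), alternative macrophage activation (0.30) and apoptosis (0.09) each had 1 member higher and none lower. The NRF2 oxidative stress list had a median of −0.21, below all random lists, with none of 17 members at 1.5-fold. Its lowest members were Blvrb (−0.47), which reduces biliverdin, and the ferritin light chain Ftl1 (−0.41).

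The interferon-stimulated genes were also higher in every other class compared. In macrophage-like cells 57 of 58 measured members were at least 1.5-fold higher, with a median log2 ratio of 2.26. Isg15 was there at 191 against 10.9 CPM and Slfn4 at 30.0 against 0.833 CPM. In neutrophil-like cells 49 of 51 were higher (median 1.98), with Ifit1, whose reads may be shared with close copies, at 76.1 against 1.53 CPM and Rsad2, the antiviral protein viperin, at 63.7 against 2.30 CPM. Monocyte-like cells had 52 of 56 higher (1.61) and progenitor-like cells 40 of 51 (1.10), with none lower in either. Dendritic cell-like cells had 50 of 57 higher and 1 lower (1.55), and B cell-like cells 47 of 56 higher and 2 lower (1.29). Both of these classes are small. Of all genes with at least 20 CPM, 9.09% were higher and 9.72% lower in B cell-like cells. The shares were 10.4% and 3.51% in dendritic cell-like cells, against 1.08% and 0.108% in osteoclast-like cells. The B cell-like vehicle cells held only 654910 UMIs together, so list members near 2 CPM rest on few UMIs there. Of 45 members measured in all 7 classes, 31 were at least 1.5-fold higher in each, including Isg15, Irf7, Stat2, Irf9, Oas2, Oasl2, Usp18 and Zbp1. Per cell, the median share of UMIs from this list was 0.292% (quartiles 0.197 and 0.449%) in osteoclast-like DHT cells and 0.152% (0.113 and 0.202%) in vehicle cells. In macrophage-like cells it was 0.602% (0.364 and 1.02%) and 0.192% (0.146 and 0.258%), so each quartile lay higher with DHT.

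**Figure D4:**
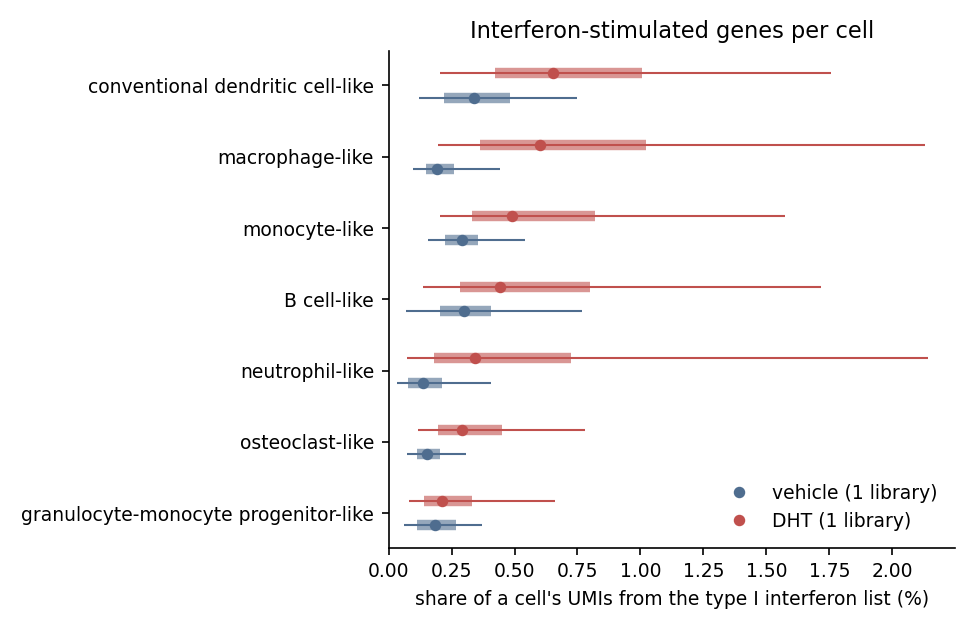
Share of a cell's UMIs that came from type I interferon-stimulated genes (x axis, %) in 7 cell classes (y axis) of the DHT and the vehicle library, 1 library each; points are medians over cells, thick bars quartiles and thin lines the central 90%. The medians were 0.292% and 0.152% in osteoclast-like cells and 0.602% and 0.192% in macrophage-like cells.

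Macrophage-like cells differed in more than interferon genes, with 216 genes at least 1.5-fold higher and 80 lower of 6599. All 30 measured G2 and M phase genes were lower in the DHT library, 20 of them by at least 1.5-fold, with a median of −0.62 against −0.07 to 0.08 for random lists. The count of 20 was 10 with no doublets removed and 27, with a median of −0.96, without the 10% of cells with the highest Scrublet score, and all 30 genes stayed below 0. Mki67 was at 185 against 302 CPM, Birc5 at 102 against 182 CPM and Cdc20 at 25.9 against 47.8 CPM. The S phase list had a median of 0.00, with 1 of 30 members lower. Alternative activation genes were higher in 6 of 10 cases (median 0.80), among them Arg1 (68.4 against 15.6 CPM) and the mannose receptor Mrc1 (92.8 against 41.0 CPM). NF-κB and inflammatory cytokine genes were higher in 14 of 39 cases (median 0.36), led by the chemokine Ccl5 at 58.3 against 1.94 CPM. Osteoclast genes went both ways, with 3 of 34 measured members higher, 3 lower and a median of 0.13. Mmp9 was 3.35-fold higher and Acp5 was at 63.0 against 41.1 CPM, while Atp6v0d2 (14.6 against 26.0 CPM) and Dcstamp (12.1 against 20.9 CPM) were lower. Neutrophil markers were higher here too, in 8 of 9 cases, and free RNA was not subtracted in this class. Median depth was lower in the DHT cells of this class (35374 against 50800 UMIs).

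Summed over all cells, 370 of 6737 genes were at least 1.5-fold higher in the DHT library and 12 were lower. The lower count was 30 and 35 with scaling by TMM and median of ratios, 63 with the mean of each cell's own CPM and 5 with the class weights below. The 12 highest were Ifit1 (log2 ratio 4.23), Slfn4 (4.06), Oasl2 (3.94), Isg15 (3.70), Irf7 (3.43), Rtp4 (3.29), Ddx60 (3.25), Zbp1 (3.24), Slfn1 (3.17), Cxcl10 (2.87), Ms4a4c (2.79) and Trim30d (2.68). The immunoglobulin gene Ighg1, at 25.1 CPM with DHT and 0 UMIs with vehicle, was also counted as higher but not ranked. The lower genes included Hmga2 (−1.22), Mmp12 (−0.92), Syngr1 (−0.88) and Mgst3 (−0.84). Of the type I list 54 of 57 members were higher and none lower, with a median of 2.00. Of the NF-κB list 21 of 39 were higher (median 0.64), among them Saa3 (1.72) and Il1b (1.70), and Chil3 (1.49) and Arg1 (1.68) were higher among the alternative activation genes. The class shares set much of this comparison. With each class given the same weight in both libraries, 95 genes were higher, 86 of them among the 370, and 44 of the 95 belonged to the interferon lists. The type I median was then 1.96 and the NF-κB median 0.18. The osteoclast list went from a median of −0.18 as sampled, with Dcstamp at −0.41, Ctsk at −0.32 and Nfatc1 at −0.30, to 0.18.

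No UMI of the 14 type I interferon alpha genes was found in either library. Ifnb1, the interferon beta gene, had 9 UMIs in 2 macrophage-like cells of the DHT library and 1 UMI in the vehicle library. Over all cells that was 0.0303 CPM (0.0139 to 0.0575) and 0.00233 CPM (up to 0.0130), but with so few cells behind these counts, no difference in these ligands is read from them.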

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

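The scalings used in this part were planned before the data were examined, and its other tests, and what each would show, were set after the results were seen. Some named genes were at least 1.5-fold higher in 1 class and at least 1.5-fold lower in another, which was not tested as a difference because each group has 1 library. Csta2, one of several near-identical stefin genes, had a log2 ratio of 2.16 in osteoclast-like cells but −1.06 (−1.21 to −0.90) in neutrophil-like cells, at 26.7 CPM with DHT and 55.5 CPM with vehicle. Mmp14 and Mmp9 had ratios of −1.76 and −1.64 in B cell-like cells, from 52 and 47 UMIs and from 106 and 88 UMIs. B cell-like cells served as the background for Mmp9. Its share of thinned cells there was 15.3% with DHT (45 of 294, 11.4 to 19.9%) and 11.5% with vehicle (6 of 52, 4.35 to 23.4%). These intervals overlap, so no direction is read from the shares. Free RNA is not excluded, so these counts are not read as expression in B cells. Psd3, lower in osteoclast-like cells, had a ratio of 0.63 (0.18 to 1.11) in B cell-like cells.

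Barcodes outside the cell filter, which the comparisons did not use, showed the interferon signal as well. In these barcodes 52 of 55 measured type I interferon-stimulated genes were at least 1.5-fold higher with DHT and none was lower, with a median log2 ratio of 1.88 against −0.23 to −0.02 for matched random lists.

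The higher level of type I interferon genes in osteoclast-like DHT cells is a pattern to which a few technical explanations apply. Free RNA from other cells is argued against, since the list's median log2 ratio was 1.71 (1.67 to 1.76) after the free RNA estimated from neutrophil markers was subtracted. Scaling and depth are argued against too: the lowest median over TMM, median of ratios, equal weight per cell and thinning was 1.66. A difference between the cultures or libraries other than DHT, such as a chance stimulus in 1 well, cannot be told apart from an effect of DHT, because there was 1 library per group. An effect of DHT therefore stays an untested hypothesis.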

How the results depend on the processing

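No paired analysis was possible because each group has 1 library. Settings that name clusters as most of their cells were, leave out the low-UMI clusters score clusters against all other cells or subtract free RNA were added after seeing the data. Scaling by TMM and median of ratios gave 30 and 35 lower genes in all cells (main 12), a type I interferon median of 1.66 under both and an osteoclast list median of 0.13 under both. The mean of each cell's own CPM gave 63 lower genes in all cells. The same class weights in both libraries gave 95 higher and 5 lower, and turned Btg2 (−0.058), Irf8 (−0.10) and Slc7a11 (−0.23) below 0. CPM minimums of 5, 50 and none gave 732, 152 and 4980 higher and 35, 3 and 1110 lower genes in all cells. In osteoclast-like cells they gave 140, 30 and 2761 higher and 20, 2 and 1417 lower. These follow from the number of genes counted. List members with at least 20 CPM gave an interferon median of 1.34, and those with 1 UMI in each library 2.03.

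Mitochondrial limits of 5 and 20% gave interferon medians of 1.78 and 1.55 and 3 and 2 lower genes in osteoclast-like cells, and the 5% limit an osteoclast median of 0.15. At least 1000 genes and 2000 UMIs gave 1.78, 4 and 0.16, and an osteoclast-like share ratio of 0.583 (0.561 with clusters named as most of their cells were). Removing the 10% of cells with the highest Scrublet score gave 1.67, 3 lower genes, a ratio of 0.580 and −0.035 for H2-Eb1. Resolution 0.3 gave an interferon median of 1.79. Resolution 1.0 gave 2 lower genes and an osteoclast median of 0.15, and clusters from the vehicle library alone gave 2, 0.16 (0.17 when renamed) and a ratio of 0.560. Clustering with all variable genes gave a ratio of 0.558, and 1.65 for the interferon median when renamed. Without the low-UMI clusters the ratio was 0.574. Free RNA subtraction turned Chil3 (−1.54) and Lcn2 (−0.91) in osteoclast-like cells. The cause of the changes was not tested beyond this. Clusters scored against all other cells gave an osteoclast-like share ratio of 0.587 and, in that class (cluster 3 alone), 1 lower gene and medians of 1.79 (interferon) and 0.11 (osteoclast). The largest named class was then neutrophil-like, with 115 higher and 15 lower genes and medians of 1.98 and −0.031. Neither list median changed sign within osteoclast-like cells. The neutrophil-like share ratio stayed within the range given by the limits of both shares' intervals. Of 2332 values of named genes, 1463 stayed within their counting intervals, 863 moved and 6 were counted as a change of sign. That count covers only genes at 1.5-fold in the main setting, and smaller ratios that crossed 0 are not in it. Depth limits rare transcripts: 3 counts correspond to 0.0220 CPM in osteoclast-like DHT cells.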

Other observations

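The cell filters, doublet settings and clusterings used in this part were planned before the data were examined. What each test would show was set after the results were seen, except for that of the cluster boundary. Outside the interferon genes, a few gene groups had small median differences of the same sign in several classes. NRF2 oxidative stress genes had negative medians in osteoclast-like (−0.21), macrophage-like (−0.16), neutrophil-like (−0.11), monocyte-like (−0.13) and progenitor-like cells (−0.29), all below at least 97% of matched random lists. Nuclear oxidative phosphorylation genes had medians of −0.21 in macrophage-like, −0.14 in neutrophil-like and −0.10 in monocyte-like cells, below the central 95% of random lists (−0.11 to 0.06, −0.04 to 0.13 and −0.09 to 0.04). In osteoclast-like (−0.02) and progenitor-like cells (−0.10) they lay within it, and no member reached 1.5-fold in these 5 classes. Unfolded protein response genes had medians above 0 in the same 5 classes, between 0.11 and 0.28, and below 0 in dendritic cell-like cells (−0.12). Members of these lists mostly stayed within 1.5-fold.

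Alternative activation genes had positive medians in macrophage-like (0.80), neutrophil-like (0.45) and monocyte-like cells (0.39), with 6 of 10, 4 of 8 and 2 of 10 members at least 1.5-fold higher (1 lower in neutrophil-like cells), and a median of 0.06 in progenitor-like cells. In osteoclast-like cells (0.30) the only member at 1.5-fold was Chil3, which turned to −1.54 after free RNA was subtracted. Free RNA was not subtracted in the other classes, so its part in their ratios was not tested. In progenitor-like cells 6 of 35 measured osteoclast genes were at least 1.5-fold lower with DHT and 2 higher, with a median of −0.06. Interferon gamma had 19 UMIs in 346 B cell-like DHT cells and 8 UMIs in 118 vehicle cells, so its level of 7.75 and 12.2 CPM rests on few molecules.

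The lower share of osteoclast-like cells with DHT was weighed against technical explanations. More cells of other lineages in the DHT library do not account for all of it: among osteoclast-, macrophage-, monocyte- and progenitor-like cells the ratio of shares was 0.723 (0.691 to 0.757), nearer to 1 but still below it. Among osteoclast- and macrophage-like cells alone the shares were 70.2% (68.5 to 71.7%) and 81.5% (80.5 to 82.5%). A ratio of shares also nears 1 when fewer other classes are counted. These values therefore do not show that part of the difference lies in the numbers of other cells. Macrophage-like cells were 12.4% and 12.6% of all retained cells. The low-UMI cluster with macrophage markers (930 DHT and 383 vehicle cells) was left out of the 2 shares above, and counting it would widen the gap between them. The cell filter and doublet removal are argued against, as the ratio nearest 1 over 5 other settings was 0.583. Open are a difference between the cultures or libraries other than DHT, such as plating density or the loss of large cells before loading, and an effect of DHT on differentiation, since there was 1 library per group.

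The lower G2 and M phase genes in macrophage-like DHT cells could reflect where the cluster's boundary fell. A test written before its result was seen argued only against a boundary particular to 1 clustering or cell filter. Over the other clusterings and cell filters the median log2 ratio nearest 0 was −0.52 (−0.57 to −0.48). None of these left out cell cycle genes, so a boundary that such genes set in every clustering is not excluded. A scaling difference common to all genes is argued against by the S phase list, whose median in the same cells was 0.0022 (−0.05 to 0.02). That list cannot decide whether the lower depth of the DHT cells (median 35374 against 50800 UMIs) bears on G2 and M phase genes in particular. Fewer macrophage-like cells in the late cell cycle in that culture is a candidate explanation, as a hypothesis. In osteoclast-like cells no G2 and M phase gene reached 1.5-fold. The pattern was found and tested on these 2 libraries only.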
